A study of Homo sapiens with 4 samples.

How the data were processed

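Total RNA from PC-9 cells was sequenced in 4 libraries, 2 labelled GPM6B overexpression and 2 labelled control, each from a single well per the labels. No label says whether the wells were transduced or harvested separately, so limma p-values measure the spread between wells, which may be technical. The labels call the control cells wild type and unloaded, while the labels' protocols name a control virus.

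The values used are TPM per transcript as deposited by the authors in a single table. Per the submitters' processing notes, cutadapt, TopHat2 and Bowtie were used with the hg38 build, with no versions. The tool that estimated TPM, its annotation release and its use of strand are not given in the sources used here. TPM of each library sum to a fixed total, so a very abundant transcript lowers all others, and neither read counts nor depth can be had from them. No counting interval or detection limit is therefore given, and a value of 0 is reported only as listed at 0.

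The table's columns are named C and E with the numbers 1 and 2. These letters match no label word for word. They were read as the initials of control and expression, and the numbers as those in the sample titles, after the low level of GPM6B had been seen and before that of CTSG. The reading is provisional and was not changed afterwards, since values must not decide which library is which. Both columns of a letter were treated as replicates. No column was left out.

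Of 252301 transcript identifiers, 202848 (80.4%) matched GENCODE release 29 (hg38), and they held 94.0% to 94.1% of TPM in each library. The other 49453 were used only in the transcript test. TPM were summed over the matched transcripts of each gene, giving 58519 genes. Genes were tested at a mean of at least 1 TPM over the 4 libraries on log2(TPM + 1), with E minus C as the direction, using limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). Folds are on the log2(TPM + 1) scale and understate changes of low genes. GPM6B lies under the filter and was tested among the 26261 genes above 0. The prior degrees of freedom were 3.19 and the total 5.19. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

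Before the data were examined, 38 gene lists were fixed, and 34 had at least 5 tested members. They were tested with camera from limma with a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. With the preset, camera judges a list against the spread across genes, so its p-values do not measure the spread between wells. With an estimated correlation it uses the residual degrees of freedom of the libraries. Of 723 list entries 1 matched no gene. The genes to be named were also fixed beforehand: GPM6B and its relatives; among protein-coding genes past the threshold whose libraries do not overlap, the 12 with the largest difference in each direction; and per list up to 4 members past the threshold, or, where a called list had none, the 2 with the smallest p. HSPA5, COL1A1, CD68, CDH5, the overlapping genes, the noncoding genes called with a library left out, FTH1 and the genes of the closing section other than these were named after their values were seen. All tests in which CTSG is removed, and the secretory and lysosomal gene families of the closing section, were chosen after seeing the data.

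The alternatives were a pseudocount of 0.1 or 5 TPM, no filter or a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, removal of GPM6B and mitochondrial genes with rescaling, no mean-variance trend, robust empirical Bayes, the replicate number as a block, leaving out each library, protein-coding genes only, and an absolute log2 difference of at least 1. Rescaling after removal was over matched genes only, so slightly more genes passed the filter. The procedure was tested on simulated data of 13646 genes, 200 of them changed, in 10 runs. Of genes changed by 2-fold 71.5% were recovered, of those changed by 4-fold 97.2%, and 5.17% of calls were false. The changed genes were drawn from those above about 5 TPM. Variances followed the model that limma assumes and genes were independent. These shares therefore need not hold for the real libraries or for lower genes.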

Results

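RNA was measured in 4 libraries from PC-9 cells, an established human lung adenocarcinoma line. Per the labels, 2 libraries came from cells given a virus to overexpress GPM6B, a neuronal membrane glycoprotein, and 2 from control cells, which some labels call unloaded and wild type while the labels' protocols name a control virus. Each library came from its own well, also per the labels. The table names its columns only by the letters C and E with the numbers 1 and 2, and no label spells the letters out. C was read as the initial of control and E as that of expression, which is a provisional reading, so the libraries are called C libraries and E libraries throughout. The values are TPM, a length-normalised relative abundance that keeps no read depth, so the depth of each library is unknown and no counting interval is given. The libraries held between 13580 and 13725 genes at 1 TPM or more. Across genes, which are not independent replicates, Pearson's r on the log2 scale was 0.983 within each letter and 0.979 to 0.981 between letters.

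GPM6B, the gene the study targeted, was near 0 in every library. It stood at 0.27 and 0.12 TPM in the C libraries and at 0.29 and 0.24 TPM in the E libraries. Tested without the filter on low values, the E minus C difference was 0.08 on the log2(TPM + 1) scale (SE 0.095, 95% confidence interval −0.18 to 0.35, limma adjusted p = 0.767), and it was −0.0060 without the second C library. The difference was thus smaller than its error, and the values bear out neither the GPM6B label of the E libraries nor a reading with the letters exchanged. These values are summed over transcripts. The coding transcript ENST00000454189 stood at 0.05 and 0.02 TPM in the C libraries and 0.26 and 0.24 TPM in the E libraries. Another, ENST00000316715, ran the other way, at 0.22 and 0.1 TPM against 0.03 and 0 TPM. Both lay under the filter on low values in the main transcript test. GPM6B (ENSG00000046653) lies on the minus strand of chromosome X from 13771031 to 13938638 in hg38. Its relative GPM6A was as low, at 0.47 and 0.13 TPM in the C libraries and 0.02 and 0.06 TPM in the E libraries.

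CTSG, which encodes cathepsin G, a serine protease of neutrophil granules, separated the libraries most sharply. It stood at 23621 and 21061 TPM in the C libraries, where it was the most abundant gene and took 2.36% and 2.11% of all TPM. It was listed at 0 in both E libraries, in which FTH1 was the most abundant gene. No fold is given against a value of 0 without counts (limma adjusted p = 2.27e-07). CTSG (ENSG00000100448) lies on the minus strand of chromosome 14 from 24573522 to 24576260 in hg38. No label mentions this gene. Every difference described next therefore accompanies a difference in CTSG, with none detected in GPM6B summed over its transcripts, and is not ascribed to GPM6B. If the letters were read wrongly, each direction holds between the C and E libraries but reverses between the labelled groups.

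**Figure D1:**
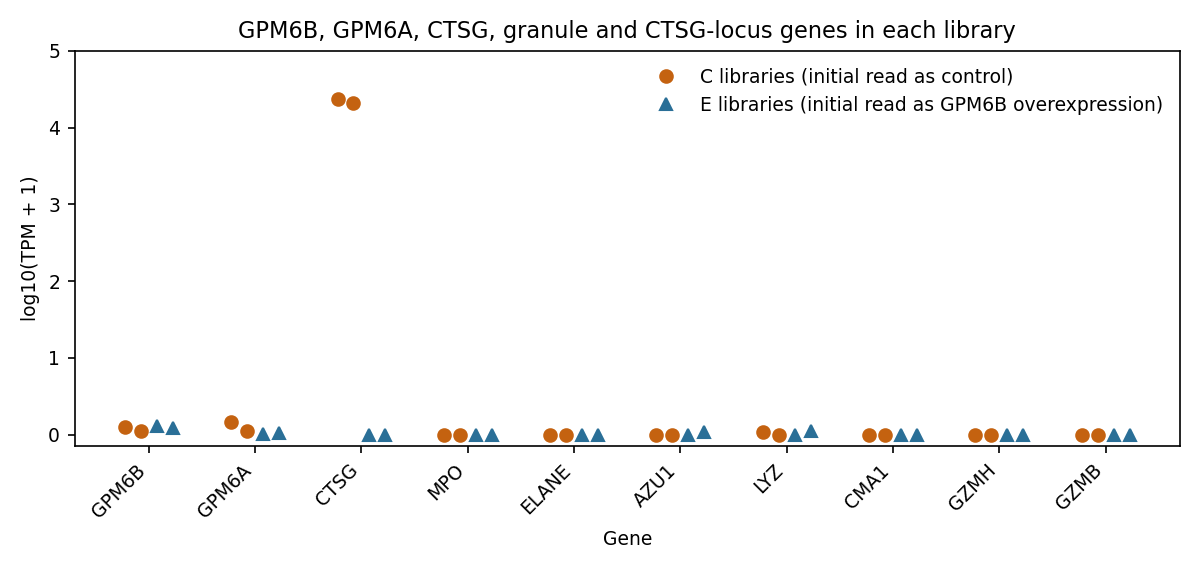
TPM of GPM6B, GPM6A, CTSG, neutrophil granule genes and neighbours of CTSG in each library, as log10(TPM + 1) on the vertical axis, with 1 point per library (C as circles, E as triangles). CTSG stands at 23621 and 21061 TPM in the C libraries and at 0 in both E libraries, while GPM6B stays under 0.3 TPM in all 4.

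Among the genes higher in the C libraries were some that act at the endoplasmic reticulum (ER) or in traffic from and to it. AGR2, a disulfide isomerase relative of secretory epithelia, averaged 303 ± 0.997 TPM (SD, n = 2) in the C libraries and 75.5 ± 0.290 TPM in the E libraries, 3.97-fold higher on the log2(TPM + 1) scale (limma adjusted p = 0.000278). PDIA4, an ER disulfide isomerase, averaged 88.7 ± 3.63 and 18.3 ± 1.27 TPM, 4.65-fold higher (limma adjusted p = 0.00249). The ER chaperones HSP90B1 and HSPA5 were 2.17-fold and 2.04-fold higher in the C libraries, and the calcium-binding chaperone CALR was 1.89-fold higher at 719 ± 31.7 against 380 ± 8.69 TPM. MANF and SDF2L1, which are induced by ER stress, were 2.38-fold and 2.84-fold higher. The trafficking genes KDELR3, which returns ER residents from the Golgi, and SEC24D, of the COPII coat, were 2.41-fold and 2.52-fold higher. AGR2 (ENSG00000106541) lies on chromosome 7 from 16791811 to 16833433 and PDIA4 (ENSG00000155660) on the same chromosome from 149003062 to 149028641, both on the minus strand in hg38.

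Of the 18 tested members of the unfolded protein response list, 10 were higher in the C libraries and 8 did not pass over all genes. Adjusted over the list alone, 15 were higher in the C libraries and 0 in the E libraries, where 0 members also had an unadjusted limma p under 0.05 in that direction. The list's median E minus C difference was −0.75 on the log2 scale (camera adjusted p = 5.29e-23). The call was lost with an estimated correlation between genes (adjusted p = 0.346), while fry, which asks whether a list's own genes move one way, gave an adjusted p of 0.0424. The ATF4 and amino acid response list did not pass. Of its 21 tested members 0 passed over all genes by limma, with 5 higher and 2 lower in the E libraries at an unadjusted p under 0.05.

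**Figure D2:**
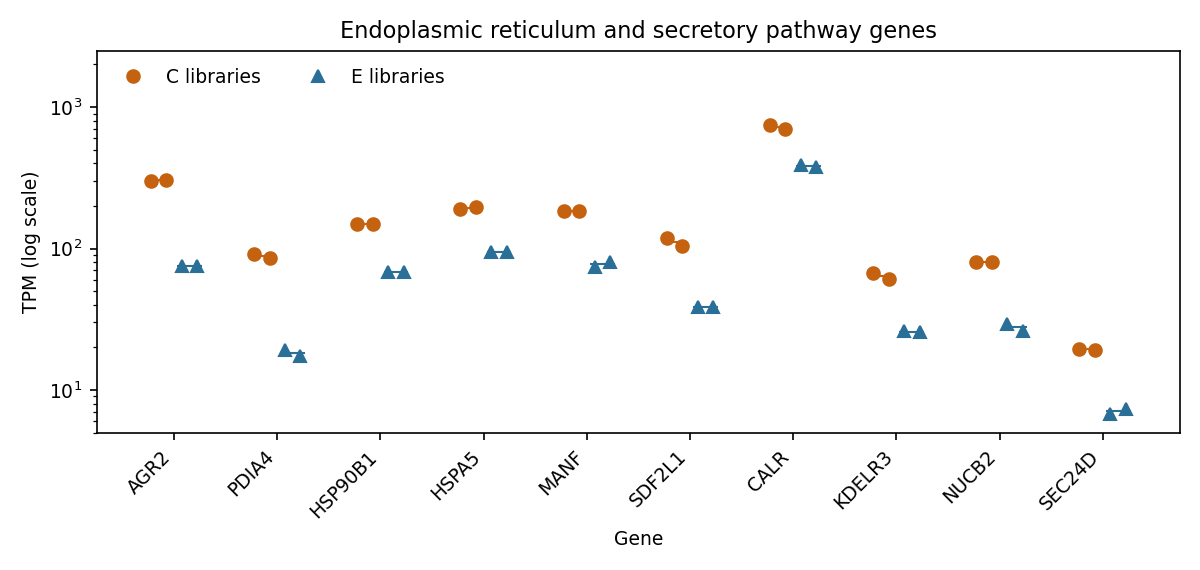
TPM of 10 ER and secretory pathway genes in each library on a log axis, with 1 point per library (C as circles, E as triangles) and a line at each mean of 2. For every gene drawn, both C libraries lie above both E libraries, by 1.89-fold for CALR up to 4.65-fold for PDIA4 on the log2(TPM + 1) scale.

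Over all 13646 genes tested, 69 were higher in the C libraries and 14 were higher in the E libraries at a limma adjusted p under 0.05, and all were protein-coding. Other genes high among the 69 were NUCB2, a calcium-binding protein of the secretory pathway, at 2.82-fold, the cyclin family gene CCNP at 5.09-fold, SMCO4 at 3.56-fold and CEP152, a centriole duplication gene, at 2.71-fold. The folds of the last 3 rest on the pseudocount: with 5 and 0.1 TPM the E minus C log2 differences were −0.90 and −4.75 for CCNP, −1.14 and −2.15 for SMCO4, and −0.69 and −1.94 for CEP152. CCNP averaged only 4.46 ± 0.622 TPM in the C libraries and 0.070 ± 0.028 TPM in the E libraries. These counts rested on all 4 libraries: genes higher in the C libraries numbered 2 without the first C library, 1 without the second C library, 1 without the first E library and 3 without the second E library, and those higher in the E libraries 1, 0, 0 and 7. None of the latter is among the 14, and all are noncoding: ENSG00000278144 without the first C library, and RNA5S2, RNA5S10, RNA5S11, RNA5S14, RNA5SP18, RNU6ATAC38P and U4 without the second E library. The genes higher in the C libraries in those fits were CTSG each time, AGR2 without the first C or the second E library, and PDIA4 without the second E library. The counts were 5 and 0 with no filter on low values, 1 and 0 without a mean-variance trend, and 159 and 114 among protein-coding genes only. At an unadjusted limma p under 0.05 the balance over the 13646 genes was the other way. Then 848 were higher in the C libraries and 1320 in the E libraries. CTSG took part of the fixed total of TPM in the C libraries only. The median E minus C difference over all genes was 0.032, and 0.00069 with CTSG removed and the rest rescaled. The unadjusted counts were not corrected for that shift.

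Among DNA replication genes, 6 of the 24 tested were higher in the C libraries and 18 did not pass over all genes. The helicase subunit MCM5 averaged 22.3 ± 0.184 TPM in the C libraries and 11.2 ± 0.205 TPM in the E libraries, 1.90-fold higher (limma adjusted p = 0.0257). CDC45, MCM6 and MCM2, which form part of the same replicative helicase, were 1.99-fold, 1.65-fold and 1.53-fold higher. Adjusted over the list alone, 13 were higher in the C libraries. All 24 had a negative E minus C difference, with a median of −0.47 (camera adjusted p = 2.50e-18, adjusted p = 0.346 with an estimated correlation, fry adjusted p = 0.0424).

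Mitosis genes leaned the other way, toward the E libraries. PLK1, a mitotic kinase, averaged 44.4 ± 2.62 TPM in the C libraries and 62.4 ± 0.219 TPM in the E libraries (limma adjusted p = 0.0679), and CDC20, an activator of the anaphase-promoting complex, 48.8 ± 1.34 and 62.8 ± 0.375 TPM (limma adjusted p = 0.0789). Over all genes 0 of the 24 members passed by limma, although 13 had an unadjusted p under 0.05, and 11 were higher in the E libraries when adjusted over the list alone. The median difference was 0.25 on the log2 scale (camera adjusted p = 7.78e-07, adjusted p = 0.346 with an estimated correlation, fry adjusted p = 0.0424).

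The 14 genes higher in the E libraries differed by 1.58-fold or less. HSPB8, a small heat shock protein, averaged 35.3 ± 2.30 TPM in the C libraries and 56.4 ± 2.07 TPM in the E libraries, 1.58-fold higher (limma adjusted p = 0.0420). TAPBP, which loads peptides onto MHC class I, was 1.53-fold higher and the histone gene H2AC6 1.44-fold higher. PLAU, an activator of plasminogen, was 1.36-fold higher. The metal-binding MT2A, the mitochondrial superoxide dismutase SOD2, the transcription factor BATF, the uridine phosphorylase UPP1, the adhesion protein ZYX, the autophagy receptor SQSTM1 and the cell cycle inhibitor gene CDKN2A were between 1.24-fold and 1.36-fold higher. With CTSG removed and the rest rescaled, 7 of the 14 kept their call. With median-of-ratios scaling 6 did. MT2A, PLAU, UPP1, ZYX and CDKN2A were among those lost under that scaling (limma adjusted p from 0.0571 to 0.0717). The median E minus C difference over all genes was 0.032, and 0.00069 with CTSG removed.

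Lists of MHC class I, inflammatory and adhesion genes lay toward the E libraries. None of these lists passed fry (adjusted p = 0.0532, 0.0761 and 0.106 in that order). Of 17 MHC class I presentation genes, TAPBP was higher in the E libraries, CALR was higher in the C libraries and 15 did not pass, and 7 and 2 passed in those directions when adjusted over the list alone (camera adjusted p = 0.000366, adjusted p = 0.346 with an estimated correlation). Of 22 integrin and focal adhesion genes, ZYX passed over all genes, 21 did not, and 6 were higher in the E libraries when adjusted over the list alone (camera adjusted p = 2.85e-05, adjusted p = 0.458 with an estimated correlation). Of 19 NF-kB and inflammatory cytokine genes 0 passed over all genes by limma, 11 had an unadjusted p under 0.05 and 9 were higher in the E libraries when adjusted over the list alone (camera adjusted p = 0.000310, adjusted p = 0.355 with an estimated correlation). Among them TNFAIP2 averaged 631 ± 33.3 and 779 ± 12.9 TPM, and NFKBIA, the NF-kB inhibitor, 93.0 ± 2.74 and 115 ± 0.453 TPM in the C and E libraries.

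H2AC6 was the member that passed among 14 replication-dependent histones and MT2A among the 5 tested members of the metallothionein list, with 13 and 4 not passing and 3 and 2 higher in the E libraries when adjusted over the list alone. Both lists lay toward the E libraries (camera adjusted p = 0.0146 and 0.0232, adjusted p = 0.445 and 0.571 with an estimated correlation). Neither passed fry (adjusted p = 0.131 for each). Both lists hold genes of families with similar sequences, so their values may be uncertain, which was not tested. Without the first C library the camera adjusted p was 0.279 and 0.315, for metallothioneins it was 0.0881 without the first E library, and for histones it was 0.0696 with no filter and 0.0664 at a mean of at least 5 TPM. The 13 mitochondrially encoded mRNAs had a median difference of 0.099, with 0 passing by limma, 4 higher in the E libraries at an unadjusted p under 0.05 and 2 when adjusted over the list alone (camera adjusted p = 0.0283, adjusted p = 0.835 with an estimated correlation, fry adjusted p = 0.427). MT-ND1 averaged 2443 ± 125 and 2819 ± 104 TPM in the C and E libraries, and MT-ND2 2798 ± 138 and 3192 ± 87.7 TPM. That call was lost without the first C library (0.550), without the first E library (0.534), with median-of-ratios scaling (0.336), at a mean of at least 5 TPM (0.0544) and with CTSG removed and the rest rescaled (0.128), all as camera adjusted p.

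The glycolysis and cholesterol synthesis lists lay toward the C libraries with small differences. LDHA, which converts pyruvate to lactate, was 1.30-fold higher in the C libraries, at 585 ± 17.4 against 448 ± 6.72 TPM (limma adjusted p = 0.0405). It was the member that passed among 18 glycolysis genes, with 17 not passing and 4 higher in the C libraries when adjusted over the list alone (camera adjusted p = 0.000264, adjusted p = 0.346 with an estimated correlation, fry adjusted p = 0.0424). Of 22 cholesterol synthesis genes 0 passed by limma, 6 were higher in the C libraries at an unadjusted p under 0.05 and 0 when adjusted over the list alone (camera adjusted p = 0.00121, adjusted p = 0.458 with an estimated correlation). The cholesterol synthesis list did not pass fry (adjusted p = 0.131). SQLE averaged 38.1 ± 1.30 and 29.9 ± 1.26 TPM and HMGCS1 62.7 ± 2.46 and 51.6 ± 0.679 TPM in the C and E libraries.

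Of 19 hypoxia response genes 0 passed by limma, with 7 higher in the C libraries and 3 in the E libraries at an unadjusted p under 0.05, and 4 and 0 when adjusted over the list alone (camera adjusted p = 0.0174, adjusted p = 0.445 with an estimated correlation). The hypoxia list did not pass fry (adjusted p = 0.0873). P4HA1, a collagen prolyl hydroxylase subunit of the ER, averaged 32.7 ± 1.54 and 19.2 ± 1.70 TPM, and NDRG1 47.2 ± 2.64 and 31.6 ± 2.62 TPM. Of 19 NRF2 targets 0 passed by limma, with 6 higher in the C libraries and 3 in the E libraries at an unadjusted p under 0.05, and 4 and 2 when adjusted over the list alone (camera adjusted p = 0.0383, adjusted p = 0.445 with an estimated correlation, fry adjusted p = 0.0424). AKR1B10 averaged 439 ± 9.05 and 369 ± 6.14 TPM, while the ferritin light chain gene FTL lay the other way at 7541 ± 16.8 and 8362 ± 19.5 TPM. Both calls were lost without the second C library (camera adjusted p = 0.169 for each), without the second E library (0.0869 and 0.118) and at a mean of at least 5 TPM (0.0709 and 0.0527). That on NRF2 targets was also lost without the first E library (0.0653), with the replicate numbers as a block (0.0614) and with GPM6B and mitochondrial genes removed (0.0543).

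**Figure D3:**
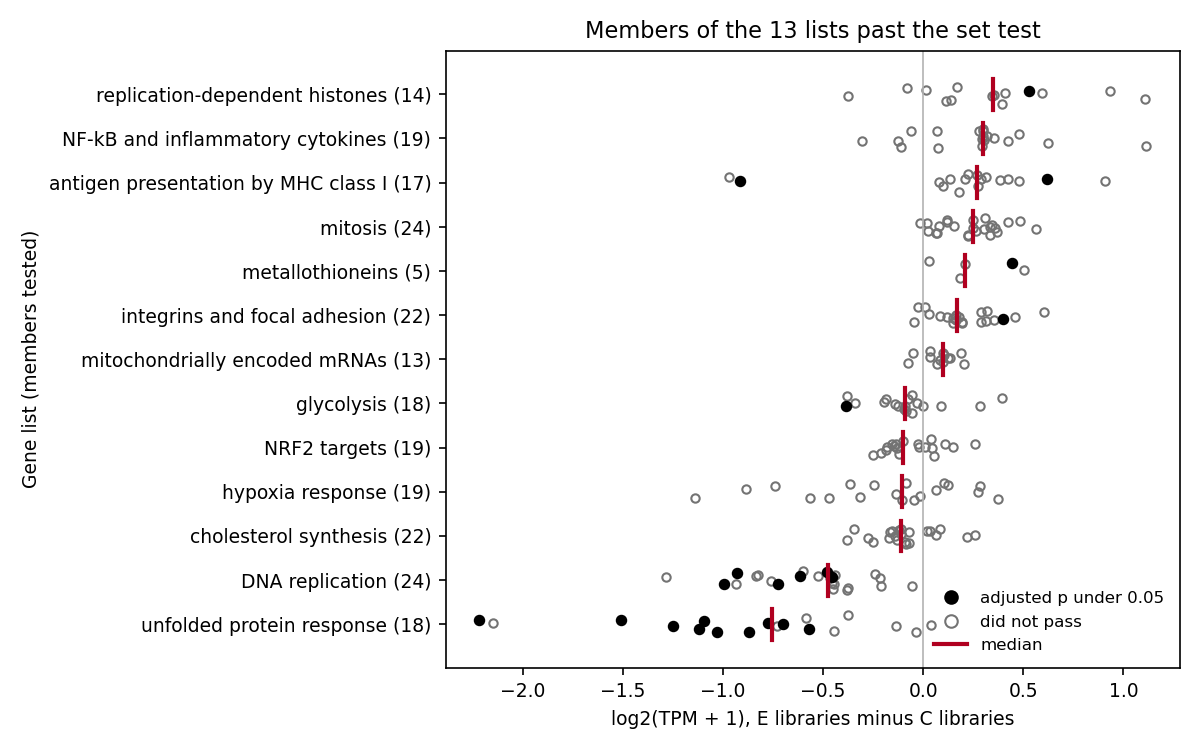
E minus C difference in log2(TPM + 1) on the horizontal axis for each tested member of the 13 lists past the camera test, with filled points for members past a limma adjusted p of 0.05, open points for the rest and a red line at each list's median. The unfolded protein response and DNA replication lists have the lowest medians, −0.75 and −0.47, and the mitosis list has a median of 0.25.

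The other 21 lists tested did not pass camera: p53 targets, apoptosis regulators, type I interferon response, EGFR and MAPK feedback, EGFR family receptors and ligands, epithelial junctions, mesenchymal transition, TGF-beta targets, matrix proteases and inhibitors, YAP, Wnt and Notch targets, fatty acid synthesis, nuclear oxidative phosphorylation, ATF4 and amino acid response, heat shock, immediate early genes, cytosolic ribosomal proteins, and lung lineage, stem cell and neural markers. In 6 of them the median, the mean and the test differed in sign, so no direction is given: EGFR and MAPK feedback, EGFR family, matrix proteases, Wnt targets, fatty acid synthesis and ribosomal proteins. Of the 21, immediate early genes passed toward the E libraries with no filter and without the second C library (camera adjusted p = 0.0379 in both), and ribosomal proteins without the second C library (0.0458). Markers of other cell types were mostly below the filter. Of the fibroblast, leukocyte and endothelial markers 2, 2 and 1 were tested and 0 passed by limma, with 0 at an unadjusted p under 0.05. COL1A1 averaged 3.17 ± 1.06 and 3.79 ± 1.34 TPM, CD68 82.7 ± 0.141 and 80.4 ± 4.34 TPM, and CDH5 7.75 ± 0.141 and 9.23 ± 0.679 TPM in the C and E libraries.

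At the level of single transcripts, 1 of 41171 tested was higher in the C libraries and 0 were higher in the E libraries by limma. The 1 transcript was the coding transcript of CTSG, ENST00000216336, at 23621 and 21060 TPM in the C libraries and listed at 0 in both E libraries (limma adjusted p = 2.63e-05). At an unadjusted p under 0.05 there were 1753 transcripts higher in the C libraries and 2215 higher in the E libraries. As for genes, these counts were not corrected for the TPM that CTSG takes in the C libraries. Both E libraries lay on the same side of both C libraries for 48.3% of genes, against 33.3% by chance. A permutation test of a single gene in 2 against 2 libraries cannot give an exact two-sided p under 0.333, so the adjusted p-values lean on the spread that limma shares across genes. Overlapping expressed genes make some values uncertain, since strand use in the counting is not given in the sources used here: SOD2 with WTAP, SQSTM1 with MRNIP and MGAT4B, ZYX with EPHA1, CDKN2A with CDKN2B-AS1, PLAU with C10orf55, HSPB8 with ENSG00000213144, HSP90B1 with UQCC6, KDELR3 with DDX17, and MCM2 with TPRA1.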

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

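Genes named by the fixed rule, other than CTSG, GPM6B and its relatives, kept their E minus C direction in each refit testing them. So did the 13 lists past the threshold. A change of filter, trend or block, or robust empirical Bayes, leaves a gene's difference as it is. Those refits could not change a gene's direction. For each of these named genes, both E libraries lay on the same side of both C libraries. Another pseudocount or a left-out library could therefore not reverse the direction either. Of the refits of named genes, only those with scaling, quantile normalization or removal of genes could. Camera does not use the empirical Bayes fit. Its values for lists without a trend and with robust empirical Bayes were therefore bound to equal those of the main fit. Of the outcomes for named genes other than CTSG, 416 were unchanged, including those of genes that passed in neither fit. Calls lost numbered 191 and calls gained 4. The removal of CTSG with rescaling was chosen after seeing the data. Genes higher and lower in the E libraries, 14 and 69, became 0 and 5 with no filter (HSPA5, CTSG, AGR2, PDIA4 and HSP90B1), 0 and 1 (CTSG) without a mean-variance trend, 114 and 159 among protein-coding genes, and 0 and 15 at an absolute log2 difference of at least 1. The higher ones became 38 at a mean of at least 5 TPM, 7 with median-of-ratios scaling and 7 with CTSG removed. Leaving out each library gave 0 to 7 higher, none of them among the 14, and 1 to 3 lower, assuming that the lone library varies like the other group. GPM6B ranged from −0.0060 (without the second C library) to 0.175 in those fits and was 0.352 with a pseudocount of 0.1 TPM, never past the threshold in any refit, and has no value where it is removed. Transcripts higher and lower, 0 and 1, became 1 and 18 at a mean of at least 5 TPM and 2 and 5 with quantile normalization. Of the 13 lists, 8 passed at a mean of at least 5 TPM, where the metallothionein list had too few members to be tested. By fry 5 passed, and with an estimated correlation 0. The estimated correlation was −0.041 for mitosis and −0.051 for glycolysis, below the preset 0.01, and 0.123 for DNA replication, above it. Calls were lost on either side, so their loss cannot be read as an effect of correlated genes alone. Camera with an estimated correlation also falls to the residual degrees of freedom of the libraries, far fewer than with the preset. The replicate numbers share only a number: with 2 pairs, the correlation of same-numbered deviations was −0.0082, computed after calls under the block had been seen. The replicate block gave 16 genes higher and 58 lower, 10 and 49 of them among those without it, and ended the call on NRF2 targets. The causes of these changes were not tested, except that a size bound, fewer libraries and fewer degrees of freedom in camera limit calls by construction. Depth is unknown, so its limit cannot be given.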

Other observations

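The gene families and the tests of swapped labels, unmatched identifiers, a CTSG construct and crowding by CTSG were chosen after the values were seen. Families chosen this way cannot test whether the difference in ER genes reaches further along the secretory pathway, and most of their members did not pass. Of 10 protein disulfide isomerases tested, 5 were higher in the C libraries over all genes, with a median E minus C difference of −0.57 on the log2 scale, and so were 2 of 10 COPII coat genes, 2 of 9 COPI coat genes, 3 of 9 TMED cargo receptors, 3 of 16 translocon genes, 2 of 11 oligosaccharyltransferase genes and 2 of 3 KDEL receptors. P4HB, the main protein disulfide isomerase, the COPII gene SEC13 and the COPI gene COPG1 had log2 differences of −0.65, −0.62 and −0.68 (limma adjusted p = 0.0153, 0.0160 and 0.0124). With an estimated correlation, camera gave the 6 secretory families large enough to test adjusted p-values from 0.0594 to 0.0918, all above 0.05. Of 10 lysosomal cathepsins and 19 V-type ATPase genes 0 passed by limma, with 3 and 5 higher and 0 and 1 lower in the E libraries at an unadjusted p under 0.05. The cathepsins had a median of 0.13 (camera adjusted p = 0.0249, adjusted p = 0.159 with an estimated correlation), with CTSD at 842 ± 6.37 TPM (SD, n = 2) in the C libraries and 927 ± 18.8 TPM in the E libraries.

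The first pattern is CTSG, at 23621 and 21061 TPM in the C libraries and listed at 0 in the E libraries. Neutrophil precursors bring other granule transcripts with CTSG, and the highest of MPO, ELANE, AZU1 and LYZ in a C library was 0.08 TPM, which argues against contamination by such cells; S100A9 stood at 588 to 661 TPM in all 4 libraries alike. CMA1, GZMH and GZMB beside CTSG were at 0 TPM in both C libraries, which argues against activation of the neighbourhood. A CTSG expression construct in the C libraries is a candidate explanation: at most 0.00318% of CTSG TPM in a C library was listed at the retained-intron transcript, though transcription of CTSG alone from its own locus may give as little. C and E are also initials of CTSG and empty, a reading no label gives, and whether the table belongs to another experiment stays open.

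The second pattern is the absence of a difference in GPM6B summed over its transcripts. Its highest value was 0.27 TPM in the C libraries and 0.29 TPM in the E libraries, which bears out neither the labels as read nor an exchange of the group labels. Reads of a construct assigned to identifiers outside the annotation used here could hide it in either letter. The highest unmatched transcript under 1 TPM in both C libraries reached 7.44 TPM or more in both E libraries. The highest the other way reached 4.10 TPM or more in both C libraries. A hidden construct was set to show at 10 TPM or more in both E libraries. Of unmatched identifiers under 1 TPM in both C libraries, 0 reached that level. The bound set for its absence, under 1 TPM in at least 1 E library, was not met either. An exchange and a hidden construct therefore both stay open. A construct with altered codons, whose reads might not align to GPM6B, was not tested and stays open.

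The third pattern is the ER gene difference, which cannot be ascribed to GPM6B. CTSG takes part of a fixed total of TPM in the C libraries, which lowers other genes there, while the unfolded protein response list was higher there, with a median E minus C difference of −0.75 (quartiles −1.11 and −0.48), so crowding by CTSG does not account for it. A response of all ER stress branches would lower the ATF4 list in the E libraries too, and 4.76% of its tested members, 1 of 21, were below −0.2 with both E libraries under both C libraries, while 3 were above 0.2. The design confounds CTSG with every other difference between the letters, so what lies behind the ER gene difference stays open.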
